A study of Mus musculus with 4 samples.

How the data were processed

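Polyadenylated RNA was sequenced from leukemia cells collected from the bone marrow of C57BL/6 mice, in 2 libraries labelled WT (replicates 4 and 5) and 2 labelled as Ybx1 knockout (replicates 1 and 3). The knockout replicate 3 carries the number 2 after RNA-seq in its title, and the other 3 libraries carry the number 1. Nothing in the labels says that the replicates come from separate animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Per the labels' protocols, mRNA was isolated with oligo dT beads, fragmented with metal ions, copied with random primers, ligated to adapters and amplified by PCR. The submitters' processing notes name CASAVA, HISAT2 2.1.0, featureCounts and DESeq2 with the genome build GRCm38, with no role or order given.

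The authors deposited 1 table with 55339 rows, each a gene symbol. Its 4 sample columns hold log2 expression values, which the authors normalized in a way not given in the sources used here. The values reach below 0, and in genes without a deposited fold change WT replicate 5 and the knockout libraries take nearly equal but not identical values, as in a shrunken log transform. In all 4449 of these genes WT replicate 4 lay above WT replicate 5, by a median of 0.19. The deposited table also gives a log2 fold change, a p-value and an adjusted p-value per gene. Its fold change column is headed as WT against knockout. Across 17185 genes it rose with knockout minus WT of the sample columns (Pearson's r = 0.78), so it is read here as knockout over WT. The signs disagree for some genes. Eya1, Ndufa5 and Hspe1 were higher in both knockout libraries than in both WT libraries, but their deposited fold changes were -5.53, -3.53 and -5.48. No counts are given, so the depth of each library is unknown and no interval or detection limit that needs depth was computed. In 30280 rows all 4 values are 0, and 24 symbols had been turned into dates, as a spreadsheet does. For 4449 rows the table lists values but no fold change. No column held values of other samples.

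A test on counts had been planned, with limma on log values as the fallback for a table without counts. The table held log2 values, a unit the plan did not foresee, so limma 3.58.1 with a mean-variance trend was run in R 4.3.3 on the log2 values as deposited, without a pseudocount. Genes with a value of at least 1 on the linear scale (0 on the log2 scale) in at least 2 libraries were tested, which left 17303. The pseudocount of 1 that the plan named for normalized values became an alternative once the unit was seen, beside the planned 0.1 and 0.5, after the log2 values had been turned back to the linear scale. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 count as called. Differences are knockout minus WT on the log2 scale, with limma's moderated standard error (SE).

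Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes, for lists with at least 5 tested members, and p-values were adjusted over the 30 lists tested. With the preset correlation camera compares a list's genes with the other genes, so its p-values do not measure the spread between samples. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera has only the few degrees of freedom that these libraries leave. Its lowest adjusted p over the 30 lists was 0.723 with all libraries. It could hardly call any list, so its failure to call a list decides neither way. Fry's test asks whether a list's genes move on balance in 1 direction, or change in either direction, and compares no list with other genes. The groups, the fallback to limma, the value filter, the thresholds, 31 gene lists with 707 genes, the leave-one-out alternatives and the rule for named genes were fixed before the data were examined. Filters of log2 5 and 7, centring, quantile normalization, every alternative that combines a setting with the removal of WT replicate 4, and the differences from WT replicate 5 alone were chosen after the values were seen, as was the decision to describe the gene lists both with and without WT replicate 4.

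The rule named Ybx1, Bcl2 and Myc in all cases. It then took the 12 called genes with the largest rise and the 12 with the largest fall, and from each list up to 4 called members, or the 2 members with the smallest limma p where none was called. No gene was called, so only the list members were left, of which 1 is not reported here. A second set was therefore added after the values had been seen. It holds genes called in the authors' deposited table, with both knockout values on 1 side of both WT values, a mean linear value of at least 5 and no predicted gene model, and takes the 12 lower and the 12 higher genes with the widest gap between the groups.

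The limma and camera steps were tested on simulated data for 17303 genes, with 50 genes changed at each of 4 sizes and, for camera, with 1 list lowered by 1, 2 or 3. With the spread of the knockout pair in both groups, limma recovered 0% of the genes changed by 1 on the log2 scale, 12% at 2, 42% at 4 and 76% at 8, and called 2 of 17103 unchanged genes. With the spread of the WT pair in the WT group, limma recovered 0% at each size. Camera called the lowered list at each size with the spread of the knockout pair, but with that of the WT pair it missed a change of 1 (adjusted p = 0.236). With no list lowered it called 0 lists. The simulated genes were independent, so the effect of correlation between genes on camera was not tested. Gene positions were taken from the GENCODE annotation of GRCm38. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots. Members of multigene families such as the Stfa, Bcl2a1 and Trim30 genes can share reads with their copies, and their values are uncertain for that reason.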

Results

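Expression was measured in leukemia cells from mouse bone marrow, with 2 libraries labelled WT and 2 labelled as Ybx1 knockout. YBX1 is a cold-shock domain protein that binds mRNA, and the series title frames the comparison as a question of mRNA stability and survival in myeloid leukemia. The deposited values are normalized log2 expression per gene, and depth is unknown because no counts are given.

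Ybx1 (chromosome 4, 119277981 to 119294604, minus strand, GRCm38) was lower in both knockout libraries, at 7.29 and 8.33, than in WT replicate 5, at 10.002, and in WT replicate 4, at 19.70. The knockout mean differed from WT replicate 5 by -2.19 log2, a 4.57-fold lower level. The WT mean was 14.85 ± 6.86 (SD, n = 2) and the knockout mean 7.81 ± 0.73 (SD, n = 2). The limma difference of -7.04 (SE 3.49) did not pass, with an adjusted p of 0.826. Without WT replicate 5 the limma difference was -11.89 and passed, and without WT replicate 4 it was -2.19 and did not pass. In the authors' deposited table the log2 fold change of Ybx1 was -9.50, with an adjusted p of 3.06e-04.

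WT replicate 4 stood apart from the other 3 libraries in most abundant genes. Actb, the cytoplasmic actin gene, reached 25.84 in WT replicate 4, against highest values of 17.25 to 18.29 in the others. The ribosomal protein genes split in this library: Rpl5 was at 20.02 and Rplp0 at 20.08, against 12.54 and 12.10 in WT replicate 5, while Rpl14 was at 5.91 and Rps29 at 5.67, against 9.12 and 8.22. Of 1242 genes with a median of at least 10 in the other libraries, 502 (40.4%) lay over 3 log2 above that median in WT replicate 4 and 588 (47.3%) over 1 log2 below it. No abundant gene, defined in the same way, lay over 3 log2 above the others in any other library. Several unrelated, less abundant genes lay in a narrow range in WT replicate 4. Phf10, Gins2, Kif20a and Edc4 were at 5.29, 5.33, 5.40 and 5.50 there, against 4.89, 6.18, 7.77 and 6.39 in WT replicate 5. Without counts it cannot be told whether such values of WT replicate 4 are measured levels. Across the 17303 tested genes, Pearson's r was 0.69 to 0.71 between WT replicate 4 and each other library, and 0.93 to 0.96 among the other 3. Genes are not independent replicates, and no p is attached to these values.

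**Figure D1:**
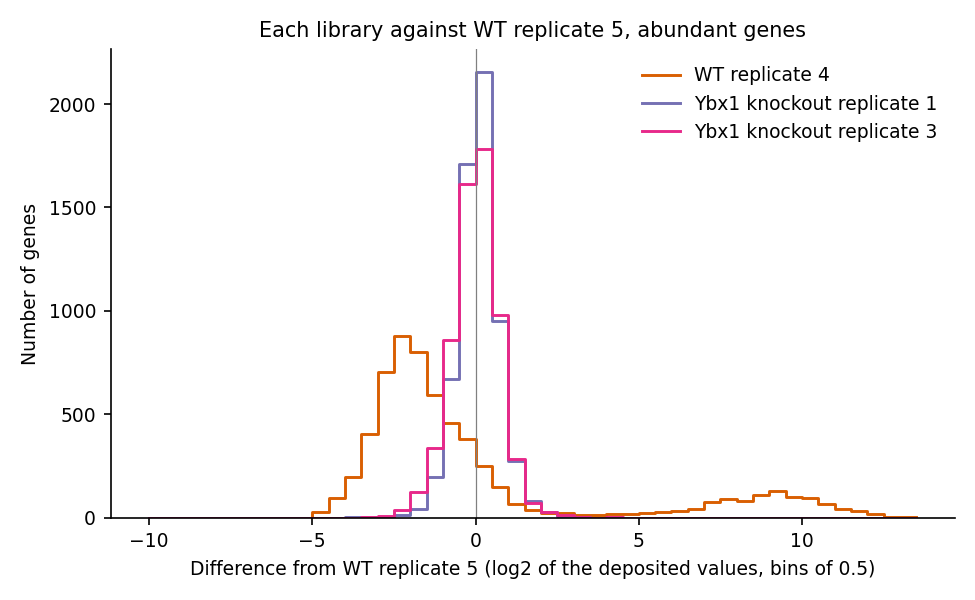
Number of genes (vertical axis) by the difference of each library from WT replicate 5 (horizontal axis, log2 of the deposited values), for 6149 genes with a median of at least 7 over WT replicate 5 and the knockout libraries. Within 1 log2 of WT replicate 5 lay 89.3% of genes in knockout replicate 1 and 85.1% in knockout replicate 3, but 20.1% in WT replicate 4, which forms a hump below 0 and a smaller hump far above it.

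Between Ybx1 knockout and WT, Ltf and Plbd1 lay lower in both knockout libraries and Phf10 and Bag1 higher, but no gene passed the test. For these 4 genes, picked after their values had been seen, the gap between the groups was wider than the difference within either pair. Ltf, which encodes lactoferrin of neutrophil secondary granules, was at 9.80 ± 1.28 (SD, n = 2) in WT and 6.43 ± 0.08 (SD, n = 2) in knockout cells, and 19.4-fold below WT replicate 5 alone. Plbd1, a phospholipase B-like gene, was at 7.95 ± 1.05 (SD, n = 2) and 5.38 ± 0.11 (SD, n = 2). Phf10, which encodes a subunit of a SWI/SNF chromatin remodelling complex, lay higher at 8.12 ± 0.38 (SD, n = 2) in knockout against 5.09 ± 0.28 (SD, n = 2) in WT cells. Its value in WT replicate 4, 5.29, lies in the narrow range described above and may not be a second measured WT level. Bag1, an HSP70 co-chaperone, was at 9.64 and 10.31 in the knockout libraries against 5.65 and 7.38 in WT.

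Limma called 0 of 17303 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.826. At an unadjusted p under 0.05 there were 651 genes, 117 higher and 534 lower in knockout. That is fewer of the 17303 genes than this threshold would let through by chance. The count rests on single libraries: limma called 4960 genes without WT replicate 5 (2452 higher, 2508 lower), 88 without knockout replicate 3, 26 without knockout replicate 1 and 0 without WT replicate 4, where 1799 genes had an unadjusted p under 0.05. Both knockout values lay below both WT values in 3248 genes (18.8%) and above them in 3000 (17.3%), where chance gives 16.7% in each direction.

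Of the genes called lower in the authors' deposited table, several had a wide gap below both WT libraries. Tnfsf9, the ligand of the costimulatory receptor 4-1BB, was at 6.09 and 5.54 in knockout against 12.40 and 8.85 in WT. Plau, the urokinase plasminogen activator, was at 0.32 and 2.54 against 12.78 and 5.70. Nfat5, a transcription factor of the osmotic stress response, was at 5.67 ± 0.30 (SD, n = 2) against 8.31 ± 0.40 (SD, n = 2). Hmga2, Lyz1, Olfm4, Camp, Trim30b and Trim30c also lay lower in both knockout libraries, with differences from WT replicate 5 of -4.12, -3.37, -1.76, -2.66, -2.20 and -5.22. After quantile normalization the limma difference of Olfm4 was 0.06 rather than -2.51.

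On the higher side were Stk11, the LKB1 kinase, at 9.50 ± 0.22 (SD, n = 2) in knockout against 7.59 ± 0.13 (SD, n = 2) in WT, and Ash2l, a core subunit of histone H3K4 methyltransferase complexes, at 10.39 ± 0.03 (SD, n = 2) against 8.53 ± 0.20 (SD, n = 2). Dapk3, a death-associated protein kinase, was at 6.57 and 7.40 in knockout against 4.87 and -0.58 in WT. Mxd4, a MAX-binding repressor, was at 6.95 and 6.73 against 5.05 and 2.94. Akr1c13, Iars2, Bambi, Ppm1f, Heatr3 and Svip lay 2.47, 2.92, 2.28, 2.55, 1.95 and 3.99 above WT replicate 5. In WT replicate 4 the same genes were at 5.26, 5.18, 5.37, 5.38, 5.36 and 4.91, which may not be measured levels. These genes were picked after their values had been seen, and limma gave each an adjusted p of 0.826, except Camp at 0.842.

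**Figure D2:**
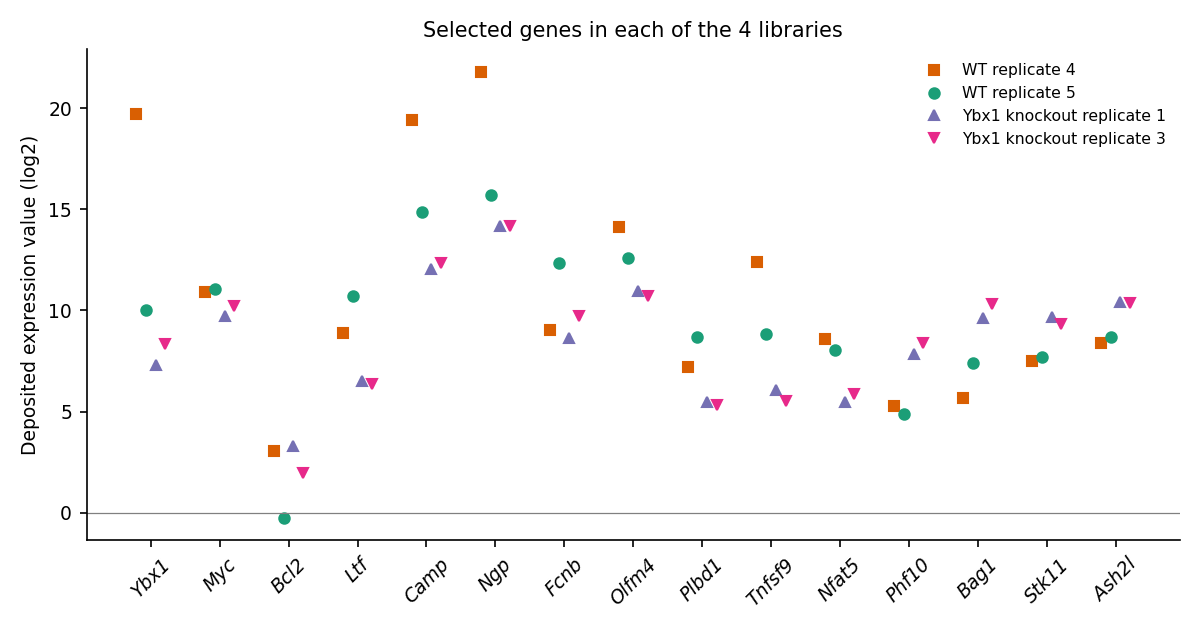
Deposited log2 expression (vertical axis) of 15 genes in each of the 4 libraries, 1 point per library. Ybx1, Myc and Bcl2 were named in advance, and the others were chosen after their values were seen. Ltf lies at 6.49 and 6.38 in the knockout libraries and at 8.90 and 10.71 in WT, while Ybx1, Camp and Ngp of WT replicate 4 lie far above the other libraries.

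Myc and Bcl2, a driver of growth and an inhibitor of apoptosis, were named in advance. Myc (chromosome 15, 61985391 to 61990374, plus strand, GRCm38) was at 9.97 ± 0.37 (SD, n = 2) in knockout and 10.98 ± 0.10 (SD, n = 2) in WT cells, with both knockout values below both WT values. Its limma difference of -1.01 (SE 1.08) did not pass, with an adjusted p of 0.829. Without WT replicate 4 the difference was -1.08 and did not pass either. In the authors' deposited table the log2 fold change of Myc was -4.82, with a p-value of 0.0103 and an adjusted p of 0.0118. Of 10330 adjusted p-values under 1 in the authors' deposited table, that of Myc is the 1 value that departs by over 0.5% from a Benjamini-Hochberg adjustment of the deposited p-values that go with them. That adjustment gives 0.0945 for Myc, and the genes next to it by deposited p-value, Tubgcp2 and Mtmr2, are listed in the authors' deposited table at 0.0945 and 0.0947. Bcl2 (chromosome 1, 106538178 to 106714274, minus strand, GRCm38) was at 3.31 and 1.95 in the knockout libraries and at 3.04 and -0.26 in WT. Its limma difference of 1.24 (SE 1.33, adjusted p = 0.829) turned to -0.41 without WT replicate 5.

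Limma called no gene of apoptosis control. Among the 7 tested pro-survival members of the BCL2 family, Mcl1 was at 9.29 and 9.68 in knockout against 8.43 and 10.52 in WT, and Bcl2l1 at 11.60 and 11.37 against 19.13 and 11.71. The authors' deposited table called Bcl2l1 lower, with a log2 fold change of -6.36 and an adjusted p of 0.0120. Of the 9 pro-apoptotic members, 4 were higher in both knockout libraries than in both WT libraries, among them Bak1 at 6.82 ± 0.12 (SD, n = 2) against 5.66 ± 0.63 (SD, n = 2) and Pmaip1 at 12.48 and 12.44 against 10.12 and 11.87. Bcl2l11, which encodes BIM, was at 7.79 and 8.79 against 8.87 and 9.77. Of 23 caspases, death receptors and regulators, 7 lay above both WT libraries, Ripk1 and Casp1 with the smallest p, and 1 below. The authors' deposited table called 1 of the 23 lower. By camera these 3 lists had adjusted p-values of 0.413, 0.252 and 0.224.

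Cell cycle genes and MYC targets were higher in knockout as groups over all 4 libraries by camera with its preset correlation. With an estimated correlation the camera adjusted p was 0.723 for each of the 3 lists, but that setting could hardly call any list with so few libraries. The same lists were low in WT replicate 4, whose median difference from WT replicate 5 was -1.80 for S phase, -1.72 for G2/M and -1.20 for MYC targets. Of 28 genes of S phase and DNA replication, 15 lay higher in both knockout libraries than in both WT libraries and 1 lower, with Gins2, a subunit of the replicative helicase complex, at 7.90 ± 0.06 (SD, n = 2) against 5.75 ± 0.61 (SD, n = 2). Of 30 genes of G2/M and mitosis, 8 lay above both WT libraries and 0 below, with the mitotic kinesin Kif20a at 8.95 ± 0.69 (SD, n = 2) against 6.58 ± 1.67 (SD, n = 2). Of 36 MYC targets and nucleolar genes, 14 lay above and 0 below, among them the spermidine synthase gene Srm at 11.46 and 11.35 against 6.08 and 10.60. The authors' deposited table called 2 S phase genes, 0 G2/M genes and 2 MYC targets lower, and 0 of each list higher. Median differences were 1.20, 1.44 and 0.69, and camera gave adjusted p-values of 8.38e-04, 8.38e-04 and 0.0478 for the 3 lists, but 0.723 for each with an estimated correlation. Without WT replicate 4 the median differences were 0.27, 0.31 and 0.18, and camera adjusted p-values were 0.0806, 0.240 and 0.0622. Without knockout replicate 1 they were 0.116, 0.339 and 0.195, and for MYC targets the camera adjusted p was also 0.0519 without WT replicate 5 and 0.0709 without knockout replicate 3. With all 4 libraries but only genes of at least log2 5 in 2 of them, a filter chosen after the values were seen, the 3 lists had camera adjusted p-values of 0.236, 0.235 and 0.911.

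With WT replicate 4 left out, secondary granule and mature neutrophil genes fell as a group, and so did monocyte and inflammatory genes, relative to the single remaining WT library. With an estimated correlation in the same 3 libraries camera called none of these 3 lists, but it could hardly call any list there. Of 24 secondary granule and mature neutrophil genes, 19 had both knockout values below WT replicate 5 and 1 above, with a median difference of -0.80. Camp, which encodes the cathelicidin peptide, was at 12.04 and 12.36 against 14.87, the granule protein gene Ngp at 14.15 and 14.19 against 15.71, and the ficolin gene Fcnb at 8.62 and 9.73 against 12.34. Against both WT libraries, 11 of the 24 lay lower in both knockout libraries and 0 higher. Camera gave an adjusted p of 2.18e-06 without WT replicate 4, 0.959 with an estimated correlation in the same libraries, and 0.142 with all 4 libraries. With all 4 libraries and the filter of log2 5 it was 6.25e-04, in the lower direction. That setting includes WT replicate 4, where many abundant genes lay far above the other libraries, Camp at 19.41 among them. A list with abundant genes can come out lower there whatever the genotype, so this value adds no independent support. The authors' deposited table called 10 of the 24 lower and 0 higher.

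The monocyte and macrophage list had a median difference of -0.88 from WT replicate 5 over 20 genes, with the transcription factor gene Klf4 at 0.23 and 2.56 against 4.36. Of 22 genes of NF-kB signalling and inflammatory cytokines, 18 had both knockout values below WT replicate 5. They included Il1b at 9.87 and 9.77 against 10.98 and the NF-kB inhibitor gene Nfkbia at 12.53 in both against 13.26. Camera adjusted p-values without WT replicate 4 were 9.04e-04 and 1.29e-04, but 0.959 for each with an estimated correlation in the same libraries, and 0.142 and 0.616 with all 4 libraries. With all 4 libraries and the filter of log2 5, camera called the NF-kB list lower (adjusted p = 0.0458). That setting again includes WT replicate 4, with Il1b at 19.44, and adds no independent support.

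Ribosomal protein and respiratory chain genes rose as groups in the same 3 libraries by camera with its preset correlation. With an estimated correlation camera called neither list, but it could hardly call any list in 3 libraries. Of 81 cytosolic ribosomal protein genes, 73 had both knockout values above WT replicate 5 and 0 below, with a median difference of 0.58 and values such as 9.02 and 9.63 against 8.22 for Rps29. Of 36 genes of oxidative phosphorylation, 25 lay above and 3 below, with a median of 0.35, and Ndufa5, a complex I subunit gene, was at 8.05 and 8.54 against 7.45. The log2 fold change of Ndufa5 in the authors' deposited table was -3.53, opposite in sign to these values. That table called 16 of the 81 ribosomal genes lower and 0 higher. Of the 36 oxidative phosphorylation genes it called 5 lower and 0 higher. The median difference over all tested genes was 0.07. Camera adjusted p-values were 2.11e-08 and 0.00159 without WT replicate 4, but 0.959 for each with an estimated correlation there, and 0.674 and 0.202 with all 4 libraries, where the ribosomal median was -1.02. With all 4 libraries and the filter of log2 5, camera called the ribosomal list lower in knockout (adjusted p = 0.0213), opposite to the direction without WT replicate 4. The spread of single genes in these fits comes from the knockout pair alone, and the WT library is assumed to vary like it. Camera p-values with the preset correlation do not measure the spread between samples. Any difference of WT replicate 5 from the knockout libraries, whatever its cause, could give such p-values.

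**Figure D3:**
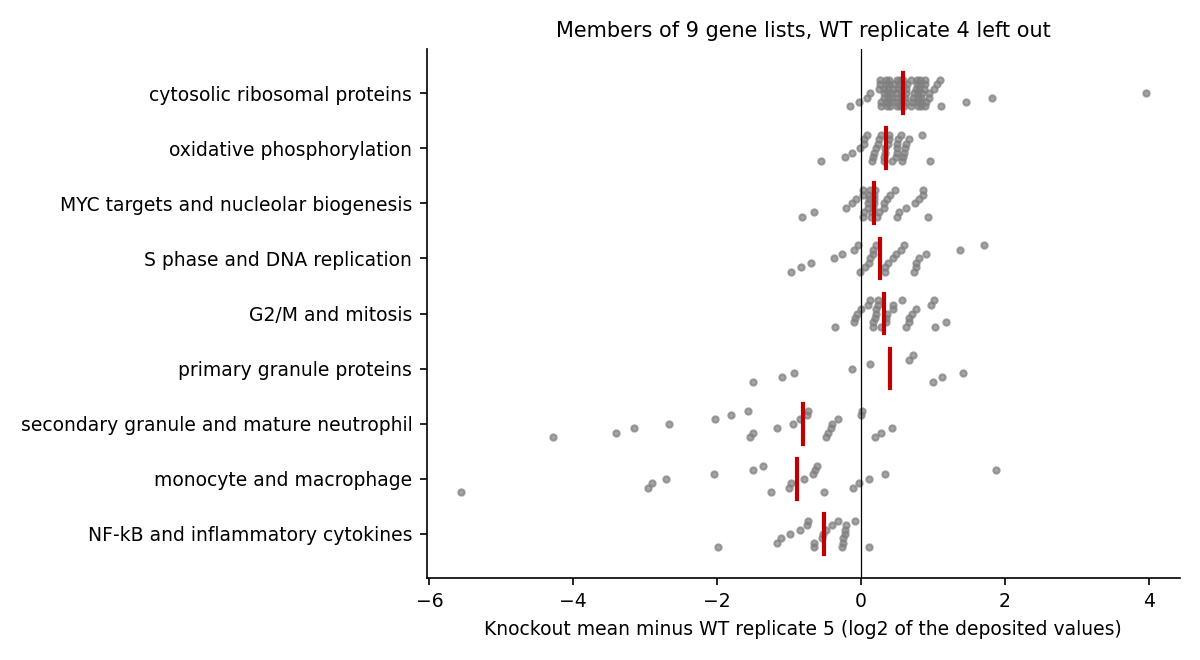
Difference of the knockout mean from WT replicate 5 (horizontal axis, log2 of the deposited values) for each tested member of 9 gene lists. Grey points are genes, spread vertically only for legibility, and red bars are list medians, which run from -0.88 for monocyte and macrophage genes to 0.58 for ribosomal proteins.

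Primary granule genes, made earlier in neutrophil development, lay on both sides. Of 10, 5 had both knockout values above WT replicate 5 and 3 below, with a median difference of 0.40, and 0 had both knockout values on 1 side of both WT values. Ctsc was at 11.24 and 11.53 in knockout against 12.32 in WT replicate 5, and Cst7 at 7.89 and 6.37 against 8.22. Elane, the neutrophil elastase gene, was at 16.48 and 16.55 in knockout against 23.52 and 15.84 in WT, and Ms4a3 at 11.33 and 11.68 against 19.91 and 10.09. The authors' deposited table called 4 of these genes lower, Ms4a3 with a log2 fold change of -7.55 and an adjusted p of 0.00346. The camera adjusted p was 0.769 with all 4 libraries and 0.417 without WT replicate 4.

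Of 26 genes of the MLL-rearranged leukemia and stem cell program, 5 lay below both WT libraries in both knockout libraries and 5 above. Eya1, a transcriptional coactivator gene, was at 9.08 ± 0.26 (SD, n = 2) in knockout against 7.11 ± 0.64 (SD, n = 2) in WT cells, and the repressor gene Gfi1 at 6.59 ± 0.17 (SD, n = 2) against 5.08 ± 0.11 (SD, n = 2). The log2 fold change of Eya1 in the authors' deposited table was -5.53, opposite in sign to these values. Cd34, a progenitor surface marker, was at 3.41 and 2.18 against 3.75 and 5.82, and Hoxa9 at 10.66 and 10.63 against 7.69 and 10.03. The camera adjusted p was 0.4998.

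Factors that mark and decay mRNA showed members on both sides. Of 22 writers, erasers and readers of m6A, a methyl mark on mRNA adenosines, 7 lay below both WT libraries and 4 above. The demethylase gene Alkbh5 was at 11.20 and 10.68 in knockout against 19.55 and 12.03 in WT, Igf2bp1 at 4.07 and 2.75 against 16.83 and 5.37, and the reader gene Ythdf3 at 7.80 ± 0.16 (SD, n = 2) against 6.02 ± 0.72 (SD, n = 2). Of 28 deadenylation, decapping and decay genes, 6 lay below and 7 above, with the decapping scaffold gene Edc4 at 7.77 ± 0.12 (SD, n = 2) against 5.94 ± 0.63 (SD, n = 2). Among 11 cold-shock proteins and YBX1 partners, Ybx3 was at 6.82 and 6.61 against 7.05 and 7.56. Camera adjusted p-values were 0.4998, 0.202 and 0.845.

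Markers of other cell types were mostly near the low end of the scale. Of 8 tested B cell genes, 3 lay below both WT libraries, among them Igkc at -1.41 and -1.71 in knockout against 2.81 and 2.88, and Fcrla. Of 11 erythroid genes, 2 lay below both WT libraries and 1 above. Alas2, the erythroid heme synthesis gene, was at -0.39 and -0.03 against 2.96 and 3.33, while the carbonic anhydrase gene Car2 lay higher at 7.42 and 8.38 against 5.21 and 6.18. The authors' deposited table called Car2 higher, with a log2 fold change of 3.09 and an adjusted p of 0.0400. Ear6 and Prg2 of eosinophils were at 0.71 ± 0.41 (SD, n = 2) and 0.29 ± 2.57 (SD, n = 2) against 3.83 ± 0.43 (SD, n = 2) and 6.34 ± 3.22 (SD, n = 2). Adjusted over the list alone, limma called Igkc and Fcrla of the B cell list (adjusted p = 0.00281 and 0.0495), Alas2 of the erythroid list (0.0336) and Uty of the sex-linked list (0.0442), and 0 other members of these lists. Camera adjusted p-values were 0.0564 for B cell, 0.142 for erythroid, 0.202 for eosinophil, basophil and mast cell, 0.202 for T and NK cell, 0.471 for megakaryocyte and platelet, and 0.4998 for dendritic cell genes. The stroma and endothelium list had 4 tested members, too few for the test.

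Sex-linked genes separated WT replicate 5 from the knockout libraries. Xist, expressed from the inactive X chromosome, was at 9.17 and 8.06 in knockout against -0.57 in WT replicate 5 and 5.07 in WT replicate 4. The Y-linked genes Uty, Ddx3y and Eif2s3y were at 7.91, 8.21 and 8.20 in WT replicate 5, at -1.23, -0.71 and 1.16 in knockout replicate 1, at 0.34, 4.11 and 3.69 in knockout replicate 3, and at 4.37, 4.90 and 4.72 in WT replicate 4. Unrelated genes lay near these levels in WT replicate 4 too, such as Diablo and Gins1 at 4.89 each. Its values for Xist and the Y-linked genes therefore do not show the sex of that sample.

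The authors' deposited table called 816 genes at an adjusted p under 0.05, of which 789 (96.7%) were lower and 27 higher in knockout. For the 789 genes called lower, the median log2 fold change in the authors' deposited table was -7.05. Over the same genes the knockout mean lay a median of -7.61 from WT replicate 4 and -0.19 from WT replicate 5. It lay above WT replicate 5 in 322 of them and at least 1 log2 below it in 119 (15.1%). Both knockout values lay below both WT values in 280 (35.5%). For the 27 genes the authors' deposited table called higher, the median difference was 2.01 from WT replicate 4 and 2.59 from WT replicate 5, and 26 had both knockout values above both WT values. Across 17185 genes, the fold change in the authors' deposited table had a Pearson's r of 0.77 with the knockout mean minus WT replicate 4 and 0.27 with the knockout mean minus WT replicate 5. Of the 816 genes, 708 were among those tested here and limma gave 36 an unadjusted p under 0.05. That is near the share of the 708 that this threshold would let through by chance.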

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

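The alternatives with a pseudocount of 1, filters of log2 5 and 7, centring, quantile normalization, a combination with the removal of WT replicate 4, and the 3 added readings of the authors' table were chosen only after the results were seen. No paired analysis was possible because the WT libraries carry the numbers 4 and 5 and the knockout libraries 1 and 3, so no number is shared. The planned count-based normalizations, count tests, voom weights and CPM filter were not run, since the table holds no counts. Limma called 0 genes under every pseudocount, filter and scaling, with 64 to 684 genes at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 4960 calls, 0 to 2452 higher, 0 to 2508 lower and 0 to 4741 with at least 2-fold change. The WT or knockout library left alone is then assumed to vary like the other group. Ybx1 ranged from -11.89 without WT replicate 5, where it passed, to -2.19 without WT replicate 4, and Bcl2 from -0.41 to 2.89. Of the other 84 named genes, limma called 51 without WT replicate 5, 6 without knockout replicate 3 and 1 without knockout replicate 1, in the direction found with all libraries. A filter of at least 5 on the linear scale left 76 of them in the test, and filters of log2 5 and 7 left 59 and 44, without Bcl2. The sign turned for 5 uncalled genes without WT replicate 4 and for 6 after quantile normalization. The median of all differences was -0.09 as deposited, -0.23 after centring and 0.16 after quantile normalization, 0.60 with a filter of log2 5 and 0.71 with log2 7.

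Camera called 3 lists with all libraries, 1 to 5 with 1 library left out, 8 without a filter on low values and 7 after quantile normalization. With a filter of log2 5 it called 4 lists and with log2 7 it called 3, all lower in knockout and none of them among the 3 of the main test. With an estimated correlation it called 0, with or without WT replicate 4, and fry called 0 in 1 direction and 0 in either. Without WT replicate 4 it called 12 lists after centring and 6 after quantile normalization. The 5 lists reported without WT replicate 4 were among both sets. Camera adjusted p for MYC targets was 0.0519 to 0.195 with 1 library left out and 0.304 with values of at least 5 on the linear scale. With filters of log2 5 and 7 it was 0.911 and 0.820 for MYC targets, 0.236 and 0.261 for S phase, and 0.235 and 0.0807 for G2/M. For S phase it was 1.65e-04 to 0.116 with 1 library left out, and for G2/M 4.69e-04 to 0.339. With an estimated correlation the adjusted p was 0.723 for each of the 3, and 0.959 without WT replicate 4. After quantile normalization without WT replicate 4 it was 0.0513 for MYC targets and 0.0521 for the other lists of the 3. Fry's adjusted p was 0.617, 0.617 and 0.688 in 1 direction, and 0.601 for each in either direction. Of the 816 calls in the authors' deposited table, 456 had an adjusted p under 0.01 and at least 2-fold change, 306 had both knockout values on 1 side of both WT values, and 146 had a knockout mean at least 1 log2 from WT replicate 5. Beyond the fewer samples or genes these settings use, the cause was not tested. Depth is unknown, so no limit from depth can be set.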

Other observations

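The tests of explanations in this part were chosen only after the results were seen, whereas the gene list tests were planned. Interferon response genes lay on both sides: Cxcl10 was at 9.55 and 9.23 in knockout against 5.70 and 8.63 in WT. Mx1, near the low end of the scale, was at -0.19 in both knockout libraries against 1.19 and 1.43. The 1.19 of WT replicate 4 may not show expression, since Gp1ba was at 1.22 there against 0.03 in WT replicate 5. Stat2, at 5.82 and 6.73 in knockout, lay between its WT values of 5.22 and 7.45. Of 31 tested interferon genes, 6 lay above both WT libraries and 2 below, and the camera adjusted p was 0.252. Against WT replicate 5 alone, 9 of these had both knockout values above and 6 below. Of 21 immediate early and heat shock genes, 7 lay below both WT libraries and 2 above, the lower ones including Fosb at 1.22 and 1.79 in knockout against 3.86 and 3.93 in WT and the phosphatase gene Dusp2 at 4.51 and 6.47 against 13.91 and 7.27. Of 26 genes of the ATF4 and unfolded protein response, 8 lay above and 2 below, with Ddit4 at 7.09 ± 0.31 (SD, n = 2) against 5.68 ± 0.64 (SD, n = 2). Camera adjusted p-values for the immediate early list and the ATF4 list were 0.346 and 0.413, and the first was 0.0458 with the filter of log2 5 and 0.0126 with log2 7.

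Among 23 p53 targets, 5 lay above both WT libraries and 2 below, but 9 above and 7 below WT replicate 5 alone. Plk3 was at 8.56 ± 0.77 (SD, n = 2) in knockout against 6.40 ± 0.98 (SD, n = 2) in WT and Perp at 0.04 ± 0.03 (SD, n = 2) against 2.97 ± 0.37 (SD, n = 2). Of 25 genes of glycolysis and hypoxia, 7 lay above both WT libraries and 6 below, with Pdk1 at 6.32 and 7.24 against 4.91 and 6.05. Mitochondrially encoded genes had 3 of 15 above and 4 below, and RNAs without a poly(A) tail had 0 of 5 in either direction. Camera adjusted p-values were 0.625 for p53 targets, 0.4998 for glycolysis, 0.845 for mitochondrial genes, 0.4998 for RNAs without a tail and 0.202 for sex-linked genes. In 10 of the 30 lists, the ribosomal proteins among them, the median, the mean and the camera direction differed in sign. The authors' deposited table gives 1565 genes with a fold change a p-value of exactly 1, and they have a median log2 fold change of -6.92.

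WT replicate 4 differs from the other libraries by amounts that vary from gene to gene. A single scaling factor would leave a small spread among abundant genes, but the SD of its difference from the others was 5.09 over 1242 genes, which argues against that account. A general rise of transcription would move ribosomal protein genes together, and their SD of 4.81, with 41 of 81 over 3 log2 above the other libraries and 32 below them, argues against it too. A candidate explanation is that few RNA molecules were sampled in this library, so that abundant genes are more often caught and then overstated. The share of genes over 3 log2 above the others rose by 47.8 percentage points from the lowest to the highest of 10 groups by level, and 21 of 22 genes at 14 or more lay that far above, but without counts other faults of library or normalization stay open.

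The deposited calls were nearly all lower in knockout. If most of those genes had mRNA levels at least 2-fold lower without YBX1, the knockout mean would also lie at least 1 log2 below WT replicate 5. It lay that far below in 15.1% of the 789 genes, which argues against a fall of that size for most of them. A smaller fall was not tested, and the knockout mean lay above WT replicate 5 in 322 of these genes. The values of WT replicate 4 may account for the direction of most calls, since the median difference from WT replicate 5 was -0.19 over the same genes and that from WT replicate 4 was -7.61. For the 119 genes with a knockout mean at least 1 log2 below WT replicate 5, such as Ltf and Tnfsf9, an effect of genotype and a difference between animals both stay open.

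Late granulocyte genes such as Ltf, Camp and Fcnb lay lower in knockout than in WT replicate 5, while of 10 primary granule genes 5 had both knockout values above it and 3 below. Fewer mature neutrophils among the knockout cells could give this pattern, but the median difference over Ly6g, Cxcr2, Retnlg, Mmp8 and Mmp9 was -0.95, with Mmp8 and Retnlg at 0.01 and -0.01, and decides neither way. A difference between animals or sexes cannot be told apart from genotype here, because Xist differed by 9.19 between the knockout mean and WT replicate 5, and WT replicate 4 gives no usable second WT level. An effect of YBX1 on these transcripts also stays open, untested.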
